A study of Drosophila melanogaster with 2 samples.

How the data were processed

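Whole embryos of both sexes, 6 to 18 hours old, from a transgenic line with GFP fused to the C terminus of Oli were used for ChIP-seq with an anti-GFP antibody, in 2 biological replicates, per the labels. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The age entry of the sample records is garbled, and the age used here is the one in the source description. There is 1 group and no second condition.

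The authors deposited 4 peak lists on the dm6 assembly, per the accompanying file notes: 1 per replicate (30000 peaks each), 1 from the pooled replicates (30000 peaks) and the IDR-thresholded list (6496 peaks). Per those notes the replicate lists and the pooled list were derived from alignments and the same control, so the replicate lists are not wholly independent. The aligner, the peak caller and their versions are not given in the sources used here. The equal, round length of the first 3 lists points to a cap on the number of peaks kept. The deposited signal of a peak is its height as the authors' caller gave it, with no further scaling stated, so it served to describe, rank and filter peaks within a list. The only use between lists was the correlation across peaks matched between replicates, and absolute sizes were not compared. The deposited -log10 q-value of a peak ran from 2.59 to 3.73 in the IDR list, where 2689 peaks shared the highest value, so it was not used for ranking. Read counts are not part of the sources used here, so depth is unknown and no limit of detection could be set. Signal tracks, alignments and control libraries were not analysed here.

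Annotation came from Ensembl release 115 (BDGP6 annotation 54) and sequence from release 6 of the Drosophila genome, which is the dm6 assembly. Peaks on 2L, 2R, 3L, 3R, 4 and X were analysed. Coordinates are counted from 1. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

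Replicates were compared over the strongest 6496 peaks of each by signal, with an overlap of at least 1 bp, against 100 random placements within chromosomes. Signals were correlated across peaks whose summits lay within 100 bp of each other. Summits within 500 bp of any annotated start site were called promoter peaks, and the rest were assigned in order to coding exon, 5' UTR, 3' UTR, non-coding exon, intron or intergenic sequence, with exact binomial 95% intervals and 100 random placements within chromosomes. The permutation p counts only the tail on the side of the observed difference, so it is one-sided, and at smallest 0.0099. The 10 E-box classes and 7 other motifs were counted within 50 bp of the summit and in an equally wide window centred 500 bp to the right of the same summit, and compared by the exact McNemar test, two-sided, with Benjamini-Hochberg adjustment over the 17 motifs. The same was done for all 2080 strand-collapsed hexamers. In windows of the same GC content on the same chromosome, 20 per peak, Fisher's exact test was used. Each peak was tied to the coding gene with the nearest start site. The members of 15 fixed gene lists with at least 1 peak were compared with all coding genes in 10 strata of territory length, the stretch in which a summit would be tied to the gene, by an exact stratified (convolved hypergeometric) test, two-sided, with Benjamini-Hochberg adjustment over the lists. All 263 symbols of the lists were found in the annotation, 4 of them under a newer name. An adjusted p under 0.05 counted as past the test. P-values are over peaks or genes in these libraries, and the spread between embryos enters only through the 2 replicates.

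The genes to be named were set by a rule before the data were examined: the nearest coding gene of each of the 15 IDR peaks with the highest signal that overlap a peak in both replicates, the 10 genes with the most IDR peaks, Oli itself, and up to 4 members of each list with the highest signal. One gene that the rule takes in is not reported here. The other named members of the motor neuron list and the ribosomal protein genes without a peak were chosen after their values were seen. The designs, the gene lists and most alternatives were also set before the data were examined.

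The tests were tested on simulated data. The gene list test, run for the gene list comparison on 13945 genes in 200 simulations, called 1.5% of lists with no effect and 99.5% of lists in which each member had a 40% chance of a peak added to the background. The lists with added peaks all had 1 size, close to that of the ribosomal protein list (92 genes). The 99.5% therefore does not give the power for the shorter lists. Simulated genes received peaks independently of their neighbours, and list members were drawn at random. Lists whose members lie side by side in the genome were therefore not covered. The hexamer test on 2080 hexamers called 0 with no effect, and ranked first a hexamer planted in 5% of the summit windows. The simulated summit and control windows had the same base composition, so a difference in GC content between summit and flank was not covered. The overlap count recovered 62.3% where 61.7% of 2000 peaks had been planted as shared.

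Alternatives covered the number of peaks (the stronger 3248 IDR peaks, or 2 times as many from the pooled list), each replicate alone, the overlap that counts as shared, the distance to a start site, the summit against the midpoint, the motif window and its control, the rule that ties a peak to a gene, the background of the gene list test and the number of peaks at one gene. Windows of the same GC content, peaks split by distance to start sites in the gene list test, overlapping peaks merged into one region and single replicates for the chromosome arms were added after seeing the data.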

Results

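Oli is a Drosophila melanogaster member of the Olig family of basic helix-loop-helix (bHLH) transcription factors, whose vertebrate relatives act in the specification of motor neurons and oligodendrocytes. Its occupancy was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos of both sexes aged 6 to 18 hours, from a transgenic line that carries Oli with green fluorescent protein (GFP) at its C terminus. Chromatin was precipitated with an antibody against GFP. The samples form 1 group of 2 biological replicates, with no second condition, so the comparisons are between the replicates, between peaks and randomly placed intervals, between summits and their flanks, and between gene lists and genes of like size. Each replicate had its own list of 30000 peaks, a list of the same length came from the pooled replicates, and 6496 peaks passed the irreproducible discovery rate (IDR) threshold. Read numbers were not given in the sources used here, so the sequencing depth behind these peaks is unknown, and each interval on a share of peaks below is an exact (Clopper-Pearson) 95% interval that covers counting error over peaks only.

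The first comparison asked how far the replicates recovered the same sites. The strongest sites were found in both: of the 500 highest peaks of replicate 1, 99.6% overlapped one of the strongest 6496 peaks of replicate 2, and 99.8% did so in the other direction. Over the strongest 6496 peaks of each replicate, 5618 (86.5%) of replicate 1 and 5224 (80.4%) of replicate 2 had a partner, a mean of 83.5%. The SD of 4.29 is between the 2 directions of 1 overlap and does not measure a spread between replicates. Random placement of one list gave 3.52%, and at most 4.05% in 100 placements. The shared fraction fell with peak strength, to 70.1% and 56.4% at ranks 4001 to 6496. A partner below rank 6496 does not count there. Against the whole list of the other replicate, 99.0% and 96.5% of the same peaks had a partner. Peak heights also ran in parallel. Across 15457 pairs of peaks with summits within 100 bp, Spearman's rho of the signal was 0.822 (0.815 to 0.828 in 200 bootstrap draws) and Pearson's r of log2 signal was 0.895. These are correlations across peaks, which are not independent replicates, and both lists were made with the same control.

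**Figure D1:**
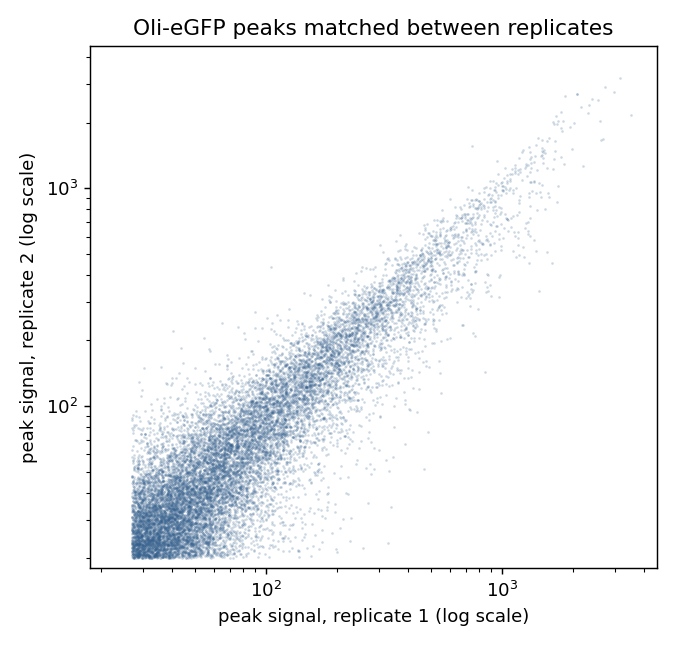
Each point is 1 of 15457 peaks matched between replicates (summits within 100 bp), with the peak signal of replicate 1 on the x axis and of replicate 2 on the y axis, both on log scales. The points follow 1 band (Spearman's rho 0.822) that widens towards low signal, and the straight lower edges are the weakest signals in the lists.

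The 6496 IDR peaks were exactly the strongest 6496 of the pooled list, down to a signal of 154.8. Of these, 6465 (99.5%) overlapped a peak in both replicate lists and 5347 (82.3%) overlapped one of the strongest 6496 peaks in both. High overlap follows from how the list was made, from the pooled replicates and with a threshold on their agreement, so it is no separate evidence of reproducibility. Their median width was 416 bp, and they covered 2345 kb, or 1.75% of the 6 chromosomes searched.

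The highest peak lay on 3L (dm6, 19590410 to 19590831), 96 bp upstream of the start site of the uncharacterised gene CG14100 (FBgn0036889), with a pooled signal of 6343 and ranks of 2 and 1 in replicates 1 and 2. The next stood on 2L (480882 to 481298) in an intron of ush, with the zinc finger gene cbt (FBgn0043364) as its nearest coding gene, 1386 bp away, and had a signal of 5703 and rank 3 in both replicates. The third stood on X (2703681 to 2704088), 36 bp upstream of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, with a signal of 5614 and ranks of 4 and 2. The reference sequence of the 41 bp around these 3 summits was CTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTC at CG14100 (3L, 19590600 to 19590640), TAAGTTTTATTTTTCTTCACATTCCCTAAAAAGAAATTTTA at cbt (2L, 481054 to 481094) and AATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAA at Ugalt (X, 2703868 to 2703908). The other genes nearest to the 15 highest peaks were CG4004, CG11050, CG13323, the arginine methyltransferase gene Art3, the mitochondrial ribosomal protein gene mRpL41, px, Trl, ph-p, Chro, PNPase, HmgZ and CG31145. Among these, Trl encodes GAGA factor (intron, 3L 14759291 to 14759742, signal 4639), ph-p a Polycomb group protein (intron, 474 bp upstream of an internal start site, X 2137171 to 2137574, signal 4537), Chro a chromatin and spindle protein (5' UTR, 3L 22878701 to 22879121, signal 4516) and HmgZ an HMG-box chromatin protein (intron, 2R 21703154 to 21703686, signal 4341). The CG4004 peak lay in an exon of the non-coding gene lncRNA:Vinr, and it had the highest signal of replicate 1 but rank 13 in replicate 2.

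Oli itself (FBgn0032651, 2L 17589184 to 17591267, plus strand) was the nearest coding gene of 7 IDR peaks. All 7 overlapped peaks in both replicates, as did 99.5% of all IDR peaks. The highest (17583100 to 17583297, rank 793, signal 803.3) lay between genes, 6024 bp upstream of the start site. Of the 3 within 500 bp of a start site, those with summits at 17588777 and 17588978 (ranks 1210 and 1931) stood 407 and 206 bp upstream of the gene. These 2 peaks overlapped each other, and the summit at 17588777 lay 57 bp from the start site of lncRNA:CR44411. The one at 17589994 (rank 2499) fell in the 5' UTR, 146 bp upstream of an internal start site of Oli. The remaining peaks had summits at 17573304, 17578275 and 17586853, between genes. With only the stronger 3248 IDR peaks Oli kept 4 peaks. The line carries tagged Oli as a transgene. Whether added copies of this sequence raised the signal here was not tested, since control libraries were not analysed.

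**Figure D2:**
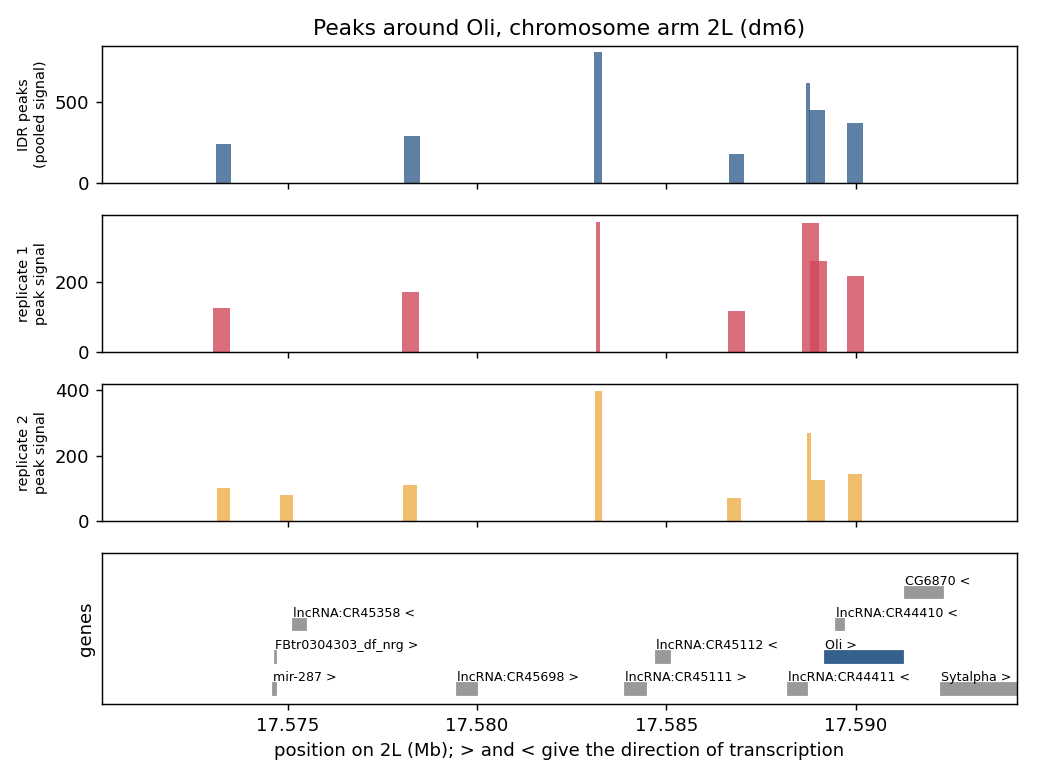
Peaks along 2L (x axis, position in Mb, dm6) around Oli, as bars as wide as each peak and as high as its signal (y axes, each list on its own scale), for the IDR peaks, replicate 1 and replicate 2, with annotated genes below. The 7 IDR peaks are found in both replicates, and the highest of the IDR peaks lies 6024 bp upstream of Oli.

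The second comparison asked where in the genome the tagged protein was recovered. Summits gathered at promoters and in introns and were nearly absent from coding exons. Within 500 bp of an annotated start site lay 2329 summits, or 35.9% (34.7 to 37.0), against 13.4% (range 12.4 to 14.4) in 100 random placements, a 2.67-fold excess (permutation p = 0.0099, the smallest the placements can give). The strongest 6496 peaks of replicates 1 and 2 gave 36.3% and 36.2%. Introns held 2814 summits (43.3%, random 39.4%), intergenic sequence 1196 (18.4%, random 27.5%), 3' UTRs 55 (0.847%, random 4.40%) and coding exons only 12 (0.185%, random 13.8%), each with permutation p = 0.0099. The smaller classes differed less: 5' UTRs held 25 summits (0.385%, random 0.609%, permutation p = 0.0198) and non-coding exons 65 (1.00%, random 0.770%, permutation p = 0.0396). Each of these p-values is one-sided, with the side taken from the data, so a two-sided p would be larger. The weakest 5000 peaks of the pooled list were unlike these, with 15.9% at promoters and 7.38% in coding exons.

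The stronger a peak, the more often it was at a promoter. The promoter share was 60.2% (55.8 to 64.5) at ranks 1 to 500, 46.6% at ranks 501 to 1000, 38.6% at ranks 1001 to 2000, 33.3% at ranks 2001 to 4000 and 29.8% (28.0 to 31.6) at ranks 4001 to 6496. Promoter summits sat just upstream of start sites: of 2146 at coding genes, 1829 (85.2%, 83.7 to 86.7) were upstream of the nearest start site, which in some cases was an internal one, with a median position of -148 bp. At the other end of the range, 1803 summits (27.8%) were more than 5 kb from the nearest coding start site. With start sites counted only within 200 bp the promoter share was 21.0%, still above random placement.

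**Figure D3:**
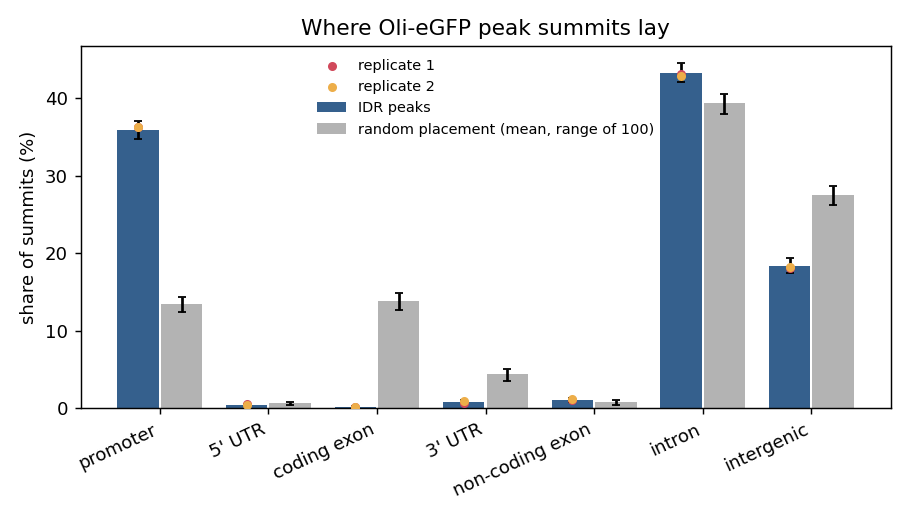
Share of summits (y axis, %) in each class of annotation (x axis, promoter first, then the rest by exon, intron and intergenic sequence) for the 6496 IDR peaks (blue bars, 95% binomial intervals), the replicates (points) and 100 random placements (grey bars, mean and range). Promoters hold 35.9% of summits against 13.4% at random, and coding exons 0.185% against 13.8%.

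Peaks were spread over the large arms, from 41.9 per Mb on 2R (1060 peaks) to 54.2 per Mb on X (1276 peaks), with 51.1 on 2L, 52.0 on 3L and 46.4 on 3R. X carried 1.15 times as many per Mb as the autosomes, 54.2 against 47.3, but in the whole pooled list it carried fewer, 206 against 228 (0.903 times). The small chromosome 4 stood apart, with 8 peaks or 5.93 per Mb (5.19 and 9.64 in replicates 1 and 2). One of the 8 (4, 1027184 to 1027406, signal 810.0), lay 184 bp upstream of PlexA, a receptor for semaphorin guidance cues. No IDR peak lay on Y.

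The third comparison asked which sequences underlie the summits, with the E-box (CANNTG), the site class of bHLH proteins, as the fixed candidate. The summits were AT-rich and did not carry more E-boxes than the sequence beside them. The GC content of the 101 bp around a summit averaged 30.9% (SD 8.21 over 6496 peaks), against 43.5% at 500 bp to the right, 43.6% at 500 bp to the left and 42.2% in the genome. It was lower at the summit than to the right in 5394 peaks (83.0%). The dip of 12.7 percentage points was 11.8 in replicate 1 and 12.4 in replicate 2, and it was 14.2 at promoters and 11.8 elsewhere. At the weakest 5000 pooled peaks it was absent, with 43.6% GC at the summit.

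**Figure D4:**
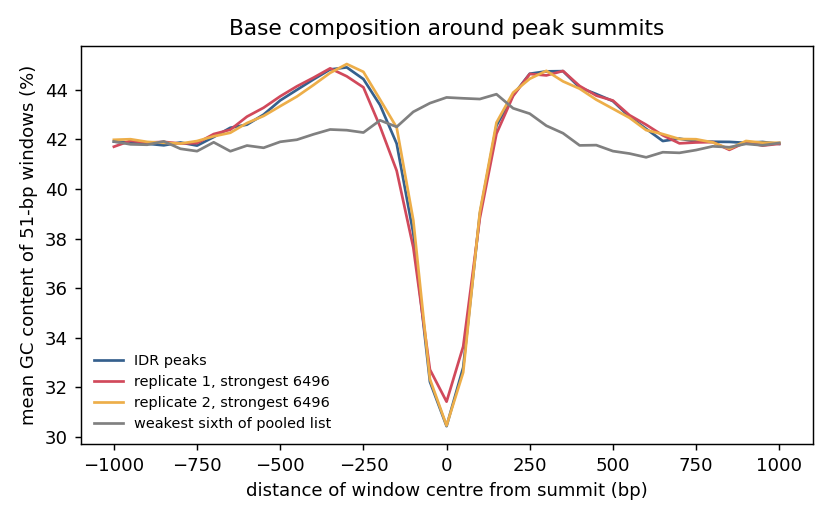
Mean GC content (y axis, %, axis starting at 30) of 51-bp windows by distance of the window's centre from the summit (x axis, bp), for the IDR peaks, the strongest 6496 peaks of each replicate and the weakest 5000 peaks of the pooled list. The first 3 lines fall together at the summit and rise above the surrounding level near 300 bp on either side, and the line of the weakest peaks shows no dip.

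Of the 10 E-box classes, 0 were more frequent within 50 bp of the summit than in the window 500 bp to the right and 7 were less frequent (exact McNemar tests, two-sided, Benjamini-Hochberg over 17 motifs; the counts were the same without adjustment and in each replicate). CACGTG was found at 33 summits and 99 flanks (0.333-fold, adjusted exact p = 1.42e-08; 0.598-fold without replicate 2, 0.553-fold in 12992 pooled peaks and 0.511-fold within 100 bp, all past the test), CACCTG at 109 and 255 (0.427-fold, adjusted p = 1.49e-14) and CAGCTG at 148 and 298 (0.497-fold, adjusted p = 1.43e-12). CATATG, the E-box preferred by mammalian Olig proteins, was found at 4.0% of summits and 3.83% of flanks (1.04-fold, adjusted exact p = 0.691). With flanks 500 bp to the left or 1000 bp to the right, CATATG was 1.23-fold more frequent at summits (adjusted exact p = 0.0311 and 0.0299), and in 2 times as many pooled peaks (12992) 1.2-fold (adjusted p = 0.00561). Because the summits were AT-rich, they were also compared with 20 random windows of the same GC content per peak, a control chosen after the base composition had been seen. Against these, 0 E-boxes were less frequent and 3 were more frequent by Fisher's exact test: CAGCTG (1.26-fold, adjusted exact p = 0.0167), CATATG (1.21-fold, adjusted p = 0.0144) and CAAGTG (1.17-fold, adjusted p = 0.0164). CAGCTG passed in each replicate alone (1.37-fold and 1.32-fold), CAAGTG only in replicate 1 and CATATG in neither (adjusted exact p = 0.191 and 0.0673).

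The sites of other factors went in both directions. The Mef2-like sequence TAWWWATA, bound by the muscle factor Mef2, was found at 23.1% of summits and 8.39% of flanks (2.75-fold, adjusted exact p = 5.5e-118), but it was no more frequent than in windows of the same GC content (0.955-fold, adjusted p = 0.0849). The GATA site WGATAR stood at 24.8% and 16.1% (1.54-fold, adjusted exact p = 1.2e-33), and 1.09-fold above windows of the same GC content. Repeats of GAGA type, the site of the GAGA factor encoded by Trl, were fewer at summits than in flanks (8.10% and 14.4%, 0.562-fold, adjusted exact p = 1.5e-29) and more frequent than at the same GC content (1.13-fold, adjusted p = 0.0144). CA repeats (CACACA) were also fewer at summits (5.02% and 11.2%, 0.448-fold, adjusted exact p = 1.0e-37; 0.859-fold at the same GC content, adjusted p = 0.0144, but not past the test in either replicate, at 0.979-fold and 0.909-fold), and the site CAGGTA of the early embryonic activator Zelda did not pass (0.805-fold, adjusted exact p = 0.106), although it did in 3 other settings: flanks 500 bp to the left (0.764-fold, adjusted exact p = 0.0317), 12992 pooled peaks (0.823-fold, adjusted p = 0.0321) and windows of 25 bp either side (0.653-fold, adjusted p = 0.0296). The promoter elements DRE, the site of the DREF protein, and Motif 1 were rare at summits and rarer in flanks, at 43 against 8 peaks (5.38-fold, adjusted exact p = 1.06e-06) and 34 against 11 peaks (3.09-fold, adjusted p = 7.93e-04). Neither passed among the stronger 3248 IDR peaks (1.86-fold and 2.0-fold, adjusted exact p = 0.320 and 0.342) or away from start sites (2.75-fold and adjusted p = 0.144 for each). Both passed against windows of the same GC content, DRE at 1.75-fold (adjusted exact p = 0.00569) and Motif 1 at 4.30-fold (adjusted p = 6.7e-10). The size of the excess was uncertain, since DRE stood at 3.2-fold without replicate 1, 2.15-fold with flanks 500 bp to the left and 2.26-fold with flanks 1000 bp to the right, and Motif 1 at 15-fold within 25 bp of the summit and 1.94-fold within 100 bp.

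All 2080 hexamers were then counted without regard to known sites. Against the flank, 534 were more frequent at summits and 1159 less frequent. The leading hexamers were ATATTA (24.2% of summits and 7.37% of flanks, 3.28-fold), TATTAA (24.3% and 7.6%, 3.19-fold) and TACTAA (8.85% and 2.89%, 3.05-fold), and each of the first 10 held at most 1 G or C. The best placed E-box by fold was CATATG, at rank 679. Against windows of the same GC content, 251 hexamers were more frequent and 189 less frequent. Among the more frequent, the lowest p-values belonged to hexamers that hold CAGTG or its reverse complement CACTG: ACAGTG (5.33% of summits and 2.87% of control windows, 1.86-fold, adjusted exact p = 1.6e-21), CAGTGC (4.94% and 2.61%, 1.90-fold, adjusted p = 1.6e-21), CACTGA (5.19% and 3.01%) and ACACTG (4.96% and 2.85%). At IDR ranks 1 to 500 alone the excess was not clear, with ACAGTG at 1.25-fold (exact p = 0.384), CAGTGC at 1.68-fold (p = 0.0407), CACTGA at 1.06-fold and ACACTG at 0.902-fold. Over all peaks the best placed E-box by fold was CAGCTG, at rank 131. These p-values are over the peaks of 2 libraries, not over embryos.

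The fourth comparison asked which genes lay nearest to the peaks. Genes for cytoplasmic ribosomal proteins had peaks far more often than genes of like territory, and odorant and gustatory receptor genes had them less often. In all, 3527 of 13945 coding genes (25.3%) were the nearest gene of at least 1 IDR peak. Of 92 cytoplasmic ribosomal protein genes 60 had a peak, where 17.4 were expected from genes with territories of the same length (3.44-fold, adjusted p = 2.4e-23, exact stratified test over 15 lists), and the replicates gave 3.24-fold and 3.63-fold. Examples are RpS27 (3R 25247381 to 25247659, 5 bp upstream of the start site, signal 1159), RpL7 (2L 10200915 to 10201156, in the 5' UTR, signal 837.3) and RpL14 (3L 8600891 to 8601036, 14 bp upstream, signal 649.8). Among the 32 without a peak were RpS3, RpL10 and RpS2. Of 119 receptor genes of the sense of smell and taste 9 had a peak, where 29.9 were expected (0.301-fold, adjusted exact p = 3.0e-06). The replicates gave 0.309-fold and 0.326-fold. The highest peaks were tied to Gr89a (signal 621.3), Gr93a, Gr93d and Or67d. Their summits stood 1345, 4137, 2478 and 64612 bp from the start sites of these genes, the last in an intron of lncRNA:CR46006. With peaks within 500 bp of start sites left out, a choice made after the data were seen, the ribosomal protein genes went to 0.412-fold (adjusted exact p = 0.272) and the receptor genes to 0.523-fold (adjusted p = 0.131), and neither list passed. With only the peaks within 500 bp of start sites both passed, at 59 of 92 ribosomal protein genes (4.85-fold, adjusted exact p = 6.8e-29) and 0 of 119 receptor genes where 17.6 were expected (adjusted p = 6.8e-08). With peaks tied to the gene whose body held the summit, 0 receptor genes had a peak and 5.02 were expected (adjusted exact p = 0.0748), while the ribosomal protein genes stood at 7.03-fold. In 12992 pooled peaks the receptor genes stood at 0.502-fold and passed.

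The 13 other lists did not pass the test. Among motor neuron transcription factors, the list that holds Oli, 9 of 13 genes had a peak and 6.53 were expected (1.38-fold, adjusted exact p = 0.496). They were B-H1, B-H2, exex, grn, Oli, tup, unc-4, vvl and zfh1, and the highest peak lay in an intron of zfh1 (3R 30781627 to 30781904, signal 1097). The highest peaks tied to vvl and tup lay between genes, 33820 and 18214 bp from the start sites of these genes. Of 30 axon guidance and target selection genes 20 had a peak against 15.3 expected (1.31-fold, adjusted exact p = 0.372), among them the netrin receptor gene unc-5 (2R 15349854 to 15350161, intron, 224 bp upstream of an internal start site, signal 1054), Sema1a (signal 952.0) and the cell adhesion gene Fas3 (signal 775.1). Of 11 homeotic genes and cofactors 9 had a peak against 5.58 expected (1.61-fold, adjusted exact p = 0.307), with 13 peaks at hth and 11 at Antp. These 3 lists passed when territory was ignored, at 2.74-fold (adjusted exact p = 0.00647), 2.64-fold (adjusted p = 2.2e-05) and 3.23-fold (adjusted p = 0.00104). Their direction was not stable, although no fold below 1 passed the test. Motor neuron factors fell to 0.650-fold with start sites counted only within 5000 bp (3 of 13 genes), 0.668-fold with gene bodies (3 of 13) and 0.765-fold with peaks near start sites alone. Axon guidance genes fell to 0.977-fold in the first of these settings and homeotic genes to 0.887-fold in the last.

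Genes of differentiated neurons had a peak in 5 of 20 cases against 8.49 expected (0.589-fold, adjusted exact p = 0.372). The pan-neuronal RNA-binding protein gene elav was one of these, with the highest peak of any member of the neural lists (X 523306 to 523677, 273 bp upstream of its start site and in an intron of arg, signal 2464, rank 74). The synaptic genes Nrx-1 (signal 830.0) and Syx1A (signal 622.5) followed. The Syx1A summit stood past the end of that gene, 6620 bp downstream of its start site, in an intron of eIF4EHP. Proneural and neuroblast genes had a peak in 11 of 22 cases (8.71 expected, adjusted exact p = 0.565), led by the asymmetric division genes brat (2L 19164990 to 19165320, intron, signal 1587) and numb (2L 9449531 to 9449805, intron, 145 bp upstream of an internal start site, signal 1499). Temporal identity genes of neuroblasts had a peak in 2 of 7 cases, grh (signal 1032) and nub (3.71 expected, adjusted exact p = 0.534). The nub summit lay between genes, 20213 bp upstream of that gene. Glial genes had a peak in 7 of 13 cases (4.08 expected, adjusted exact p = 0.372), led by the blood-brain barrier receptor gene moody (X 2050139 to 2050426, signal 1096) and the glutamine synthetase gene Gs2 (signal 1005). In the Notch pathway and Enhancer of split list 9 of 22 genes had a peak (6.59 expected, adjusted exact p = 0.534), with the highest at E(spl)m3-HLH (3R 26021161 to 26021645, signal 1764).

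The bHLH factors as a class had a peak at 14 of 41 genes against 13.8 expected (1.02-fold, adjusted exact p = 1), with the highest at crp (2L 16279674 to 16280084, intron, signal 1754) and trh (signal 1155). Muscle genes were at 13 of 29 (12.3 expected, adjusted exact p = 1), led by kirre, an adhesion protein of myoblast fusion (signal 1241), and the titin-like gene sls (signal 1148). Hemocyte and fat body genes were at 7 of 13 (4.56 expected, adjusted exact p = 0.496), led by ush (signal 1120), gut and tracheal genes at 7 of 13 (6.17 expected, adjusted p = 1), led by Hnf4 (signal 1184), and segmentation genes at 12 of 25 (11.4 expected, adjusted p = 1), led by slp2 (2L 3832362 to 3832669, signal 1658). Short lists leave wide margins, and a p-value that misses the threshold does not show that a list is like other genes.

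**Figure D5:**
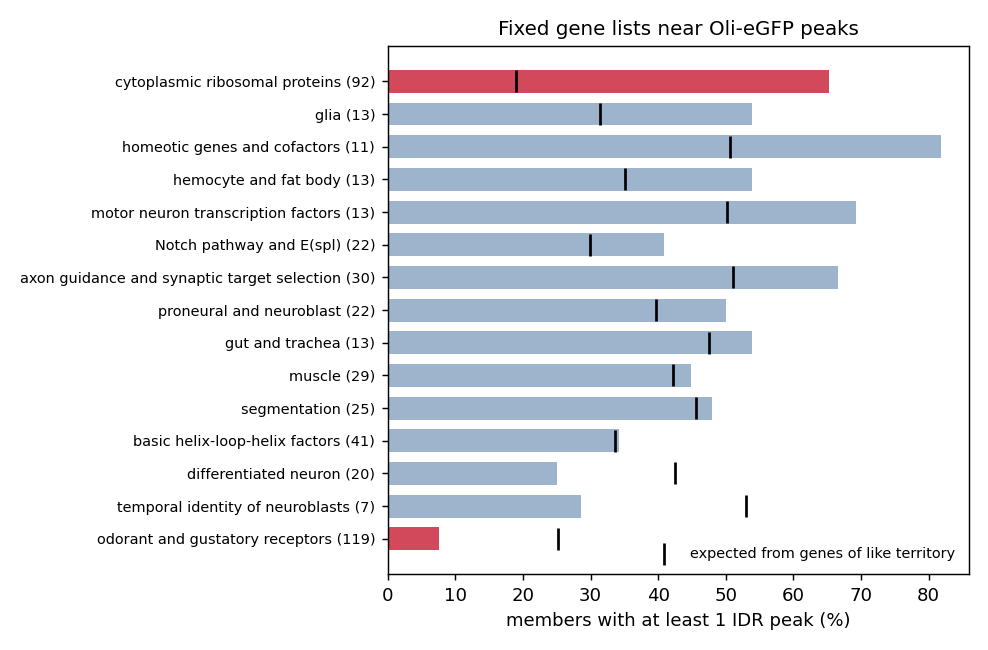
Share of the genes in each fixed list (y axis, number of genes in brackets) that are the nearest coding gene of at least 1 IDR peak (x axis, %), with black ticks at the share expected from genes of like territory and red bars where the adjusted p is below 0.05. Cytoplasmic ribosomal protein genes lie above their tick (60 of 92, 17.4 expected) and odorant and gustatory receptor genes below (9 of 119, 29.9 expected).

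Peaks also gathered at single genes. There were 223 genes with at least 5 IDR peaks, where random placement gave 146 (127 to 165 in 100 placements, permutation p = 0.0099, the smallest the placements can give), and the replicates gave 239 and 219. These genes took 1561 peaks (24.0%) and had long territories, with a median of 33.5 kb against 4.25 kb for all coding genes. The zinc finger gene shn, which acts in Dpp signalling, had the most peaks (18), followed by CG43245 (17) and by tara, rdx and the nuclear receptor gene ftz-f1 (15 each). CHES-1-like, the kinase gene Tlk, kirre, the ecdysone-induced nuclear receptor gene Eip75B and the ETS factor gene pnt had 14 each. The highest of these peaks stood in an intron of Tlk (X 3742026 to 3742408, signal 2985) and upstream of tara (3R 16222293 to 16222689, signal 2316). At the higher bar of at least 10 peaks, 33 genes were found against 28.8 at random (permutation p = 0.119).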

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

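The comparison below was chosen only after the lists had been examined. Peaks outside the strongest 6496 of each replicate, which most comparisons above leave out, also recurred between the replicates. Of the 23504 peaks ranked 6497 to 30000 in each list, 8570 (36.5%) of replicate 1 and 8568 (36.5%) of replicate 2 had a summit within 100 bp of one from the same ranks of the other replicate, against 3.51% (at most 3.86%) after random placement of peaks. Some peaks at these ranks overlapped IDR peaks. Of the IDR peaks, 99.7% and 99.8% overlapped the whole lists of replicates 1 and 2, and 89.7% and 91.7% their strongest 6496. Nearly all of the matched peaks (97.7% in each replicate) also overlapped a peak at ranks 6497 to 30000 of the pooled list. That list was made from the same 2 replicates, so this adds no separate evidence that the peaks recur. At the matched summits the GC content was 2.09 and 2.56 percentage points below the flanks in replicates 1 and 2, and at the unmatched summits the same measure was -0.586 and 0.448 points. The promoter share was 20.1% of the matched peaks in each replicate, and 20.8% and 21.7% of the unmatched.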

How the results depend on the processing

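The comparisons with windows of the same GC content, with peaks split by their distance from start sites in the gene list test, with merged peaks and with single replicates and the whole pooled list for the chromosome arms were chosen only after the results had been seen. Of 62 alternative values of the main results, 38 stayed, 23 moved and 1 changed direction. Counts stayed if within 1.5 times the main count, and the rank correlation if within its bootstrap interval. The overlap between replicates was held to the SD of its 2 directions. The share of IDR peaks found and the X ratio were held to the SD of the 2 replicates. Promoter shares counted as staying whenever they passed against random placement, whatever their size. Of 405 values for single lists, motifs and genes, 341 stayed, 14 moved, 9 fell short of the test, 11 newly passed it and 30 changed direction, 23 of these with neither value past the test. The promoter share stayed above random placement in all its alternatives, from 21.0% (200 bp) to 46.6% (1000 bp). The share of peaks found in both replicates was 76.6% with summits within 100 bp, 70.8% with at least 0.5 of each peak covered and 70.8% over the whole lists. The rank correlation of signal was 0.860 with summits within 50 bp and 0.837 among the strongest pairs. IDR peaks were found among the strongest 6496 peaks of a replicate in a mean of 90.7% of cases, 87.4% with summits within 100 bp and 83.2% with 0.5 of each peak covered. The ratio of X to autosomes was 1.202 among the stronger IDR peaks and 1.126 to 1.130 with 1 replicate left out, and it turned to 0.903 in the whole pooled list. Where a stricter overlap was used the lower shares follow from the construction; for the others the cause was not tested.

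The number of E-box classes more frequent at summits was 1 with 12992 pooled peaks, 1 with flanks 500 bp to the left, 1 with flanks 1000 bp to the right and 3 against windows of the same GC content, where 0 were less frequent. In those windows the folds turned for CAAATG (1.03), CAAGTG (1.17), CACATG (1.02), CACCTG (1.04), CAGCTG (1.26), GAGA repeats (1.13), the Zelda site (1.13) and the Mef2-like sequence (0.955), and 251 hexamers were more frequent instead of 534. The flank is richer in GC than the summit, and the matched windows remove that difference by construction. The number of gene lists past the test was 1 with peaks tied to gene bodies, 5 without territory strata and 0 with peaks over 500 bp from start sites, where ribosomal protein genes turned to 0.412-fold, which follows by construction, since 59 of the 60 with a peak had it at a start site. None of the changes of direction that follow involved a value past the test, and their cause was not tested. CATATG ranged from 0.964-fold to 1.09-fold with 1 replicate left out, and at peaks over 500 bp from start sites CAAATG turned to 1.02-fold and the Zelda site to 1.01-fold. Among gene lists, those that turned were proneural genes with the stronger 3248 peaks (0.907) and bHLH factors with 12992 pooled peaks (0.959); with start sites only within 5000 bp, motor neuron factors (0.650), gut and trachea (0.756), segmentation (0.761), bHLH factors (0.914) and axon guidance (0.977); with gene bodies, motor neuron factors (0.668), segmentation (0.737), Notch (0.834), hemocytes (0.893) and muscle (0.933); without strata, temporal identity (1.13); and with peaks within 500 bp of start sites, hemocytes (0), muscle (0.754), motor neuron factors (0.765), segmentation (0.847) and homeotic genes (0.887). Genes with at least 5 peaks numbered 59 among the stronger 3248 peaks (40.3 at random), 697 with 12992 pooled peaks (510 at random) and 219 to 239 with 1 replicate left out; 650 had at least 3 peaks (530 at random) and 33 at least 10 (28.8 at random, permutation p = 0.119). These counts follow from the number of peaks and the bar set. No paired analysis was possible because there is only 1 group. Depth is unknown, so no limit of detection can be given for genes without a peak.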

Other observations

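The 8 further gene groups, the position of CAGTG and the tests of an E-box at most summits, of summits beside one site and of a dispersed repeat were chosen only after the results had been seen. The group of chromatin genes was put together after Trl, ph-p and Chro had been seen among the highest peaks, so their high ranks are no separate finding. Of 29 genes for chromatin proteins and members of the Polycomb and trithorax groups, 15 had an IDR peak where 8.95 were expected from genes of like territory (1.68-fold, exact p = 0.0224, adjusted p = 0.0913; 17 genes in each replicate). The highest peaks of the 15 ranked from 10 at Trl, 11 at ph-p, 12 at Chro and 29 at Psc to 3671 at Su(z)2 and 4405 at CTCF. Regulators of the ecdysone response had a peak in 10 of 12 cases against 6.19 expected (1.62-fold, exact p = 0.0406, adjusted p = 0.0913), with the highest peak at Hr3 (rank 33) and the lowest at br (rank 6321). That group was put together after ftz-f1 and Eip75B had been seen among the genes with most peaks, so its test partly restates what had been seen. At the other end, 11 of 85 cytochrome P450 genes (21.5 expected, 0.512-fold, exact p = 0.00601, adjusted p = 0.0541) and 11 of 95 cuticle protein genes (19.0 expected, 0.578-fold, exact p = 0.0377, adjusted p = 0.0913) had one. The adjustment ran over 9 tests, the 8 groups and the union of 3 of them, and none of the 9 passed; over the 8 groups alone the P450 genes did (adjusted exact p = 0.0481), so their call depends on that choice. Without peaks within 500 bp of start sites the cuticle protein genes turned to 1.24-fold (10 against 8.06 expected, exact p = 0.548) and the P450 genes went to 0.735-fold (exact p = 0.356). Mitochondrial ribosomal proteins (12 of 73, 10.8 expected), proteasome subunits (7 of 48, 8.82 expected), translation factors (13 of 51, 12.0 expected) and ATP synthase subunits (3 of 15, 2.74 expected) lay near their expected counts.

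Promoter peaks at cytoplasmic ribosomal protein genes stood closer to the start site and at less AT-rich sequence than the others, a description that was not tested. Their 62 summits had a median position of -39.5 bp from the start site, with 82.3% within 100 bp of it, where the 2084 promoter summits of other coding genes had -152 bp and 23.7%. The GC content at the ribosomal summits was 43.3%, or 4.31 percentage points below the flank, against 30.8% and 14.7 points at the others. The median signals were close, 354.0 and 352.9.

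The first pattern is the AT-rich summit without a clear excess of E-boxes. A base composition bias of the libraries or the control was predicted to make the weakest peaks AT-rich too. At the weakest 5000 pooled peaks the dip was -1.93 percentage points. This cannot decide the question, because peaks are ranked by signal. A bias that raised signal at AT-rich sequence would also leave the lowest ranks without a dip. Such a bias stays open, since control libraries were not analysed here. The sequence of promoters is argued against by a dip of 11.8 points at peaks over 500 bp from any start site. Binding to an E-box at most summits is argued against by an excess of only 1.34 points in summits with any E-box over windows of the same GC content (32.3% and 30.9%). Recovery of accessible chromatin in general stays open, because other factors and GFP-only lines were not analysed here, and no biological explanation beyond E-box binding was tested, since the design has 1 group.

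The second pattern is the excess of peaks at cytoplasmic ribosomal protein genes. If promoters of broadly expressed genes were recovered in general, other such genes would share it, but mitochondrial ribosomal protein, proteasome and translation factor genes together had a peak in 32 of 172 cases against 31.6 expected (1.01-fold). These genes were gathered by symbol and not by measured expression, so not all need be broadly expressed. Peaks at any distance counted, and peaks at their promoters alone were not tested. Peaks assigned from neighbouring genes are argued against as well, since 59 of the 92 genes had a summit within 500 bp of their own start site where 12.8 were expected (4.62-fold, exact p = 3.1e-30). A preference for the most highly transcribed promoters may still lie behind the pattern, and these peak lists hold no measure of transcription or of the control. No biological explanation was tested.

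The third pattern is the position of the sequence CAGTG, which was less frequent at the summit itself than 100 bp to either side, although within 50 bp of the summit it was more frequent than in windows of the same GC content (15.99% and 9.93%, 1.61-fold), an excess not past the test at ranks 1 to 500 (10.2% and 8.51%, exact p = 0.191). It was found in 7.14% of 51-bp windows at the summit, 18.7% at 100 bp to the left, 19.6% at 100 bp to the right and 8.48% and 8.65% at 500 bp, and on either side at 33.4% of peaks (32.3 to 34.6) against 16.2% at 500 bp (2.06-fold, exact McNemar p = 9.8e-115; 1.84-fold and 2.10-fold in the replicates; 1.14-fold at the weakest 5000 pooled peaks), while CATATG there was at 1.01-fold. At ranks 1 to 500 CAGTG stood on either side at 42.4% of peaks against 16.8% (2.52-fold, exact McNemar p = 7.4e-20). CAGTG was not alone: 410 of 2080 hexamers were more frequent 100 bp from the summit than 500 bp from it. Of the first 10 by fold, 3 held CAGTG or CACTG. ACAGTG led (3.52-fold), and AGTGTA (3.15-fold) and GTGCAC (2.83-fold) were also among the 10. Promoter sequence alone is argued against by a fold of 1.97 for ACAGTG over windows of the same GC content at peaks over 500 bp from start sites, and a dispersed repeat by a soft-masked share 100 bp from the summit that was 0.960 times the share at 500 bp. Pairs of listed summits around 1 site (233 pairs of neighbouring IDR summits stood 200 to 250 bp apart) are argued against as the whole source by a fold of 2.18 at the 4925 peaks with no other pooled summit within 400 bp. Lone summits called to 1 side of their only site would have CAGTG on both sides less often than by chance. At these 4925 peaks it stood there 1.34 times as often as by chance (1.23 to 1.47), so this shortfall was not found. The ratio at 500 bp was 1.33 (1.05 to 1.67), so peaks also differ in how often they hold CAGTG. That difference raises the ratio and could hide a shortfall, so this explanation is not decided. A candidate explanation by a partner factor or another protein that binds CAGTG beside these sites stays open, which these lists cannot tell. No biological explanation was tested.

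A further hypothesis was that summits carry the extended E-box MCATATGK of mammalian Olig proteins. It was found at 1.401% of summits and 1.14% of windows of the same GC content, 1.23-fold (Fisher's exact p = 0.0558), which leaves the hypothesis undecided, since the excess lies between the sizes that would have spoken for it and against it.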
